A study of Mus musculus with 8 samples.

How the data were processed

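RNA-seq values of 8 libraries in 4 groups of 2 were used. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a SMARTer mRNA-seq kit. The submitters' processing notes name the genome builds GRCm38 and mm10. The aligner, the counting tool, their versions and the strand setting are not given in the sources used here. The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled to the library size) with 54532 genes, their length and 1 column per library, per the file headers. Multiplied by the gene length, the FPKM of a library were whole multiples of 1 step for 100% of values (within 0.01 of a read), so whole reads could be recovered from the deposited values. The authors' effective library size was 0.984 to 1.05 times the sum of those reads, and how this factor was chosen is not given in the sources used here. The recovered totals were 16544190.0 to 19125423 reads, of which 5.01% to 6.86% came from the mitochondrial genome and 5.53% to 8.28% from the 10 genes with the most reads.

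Gene identifiers, symbols, coordinates (GRCm38) and lengths were taken from the deposited table, and 98.3% of the genes also found in GENCODE M21 had the same chromosome, start and end there. Genes with a mean of at least 1 FPKM over the 8 libraries were tested, 13716 in all, of which 12326 are protein-coding. Values were put on a log2(FPKM + 1) scale and fitted with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group over all 8 libraries, eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The fit had 4 residual degrees of freedom and a median prior of 2.98. The 7 comparisons were the vector group against control, the combined against the vector group, AKG against control, the combined against the AKG group, the interaction and the 2 averages. A count model was not used as the main test because the deposited unit is FPKM.

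Gene lists of cell types and pathways were tested with limma's camera (preset inter-gene correlation of 0.01, two-sided, adjusted over the lists within a comparison), and 43 lists held at least 4 tested genes. A list's median is the median log2 difference of its tested members. Camera with an inter-gene correlation estimated from the data and limma's fry were alternatives. No list call held with either, in any of the 7 comparisons. The means of 5 lists were also compared with control by an unadjusted two-sided t-test with the spread between libraries pooled over groups, chosen after seeing the data, which only dopamine neuron genes passed. The lists, the tests, the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. The rule names the called genes with the 10 highest and 10 lowest changes or, where fewer are called, up to 5 per direction with the smallest unadjusted p, passing over Gm and Rik genes, pseudogenes and genes without a symbol. It also takes up to 4 members of each called list, and in every comparison a fixed set that includes Th, Slc6a3, Slc18a2, Gfap, Aif1, Cd68, Rheb, Sqstm1, Map1lc3b, Ogdh and Idh1. Part of these genes is printed. Ttr, Hbb-bs and the other choroid plexus and hemoglobin genes, and Slc10a4 where it was outside the rule, were chosen after their values were seen.

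Alternatives fixed beforehand were no filter on low values, a minimum of 5 FPKM, a pseudocount of 0.1, quantile normalization, median-of-ratios scaling, the replicate number as a block, eBayes without a trend, library weights, only the groups compared, and leaving out each library in turn. In the last of these the arm left with 1 library is assumed to vary like the others. Chosen after seeing the data were voom on the recovered reads with the authors' effective library sizes, protein-coding genes only, removal of a smooth trend in gene length and GC content from each library (spline with 5 degrees of freedom, GC known for 99.9% of the tested genes), and the correlation of the differences of the vector and AKG groups from control. For correlations between comparisons that share libraries, the value without any effect was simulated by giving each group's replicate deviations random signs in all 16 combinations. The tests were tried on simulated data for the vector group against control (13708 genes, 10 simulations with no library standing apart). They called 34.1% of genes changed by a log2 of 1 and 86.5% of those changed by a log2 of 2, with 6.5 false calls on average. With uncorrelated genes, camera called a 30-gene list shifted by 0.5 in 10 of 10 simulations and 0 of 400 unchanged lists. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.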

Results

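RNA from the substantia nigra, the midbrain region that holds the dopamine neurons lost in Parkinson's disease, was sequenced from male C57BL/6 mice in 4 groups of 2 libraries. The groups were wild-type controls, mice given an adeno-associated virus (AAV) carrying α-synuclein (the vector group), mice given α-ketoglutarate (AKG, a TCA cycle intermediate that the series title places in the diet) and mice given both (the combined group). α-Synuclein is the protein that aggregates in Parkinson's disease. The label of the AKG group names no vector, and the labels do not say whether the control and AKG mice received an empty one. They also do not say whether a group's 2 libraries came from separate animals, so gene p-values measure only the spread between samples, which may be technical. Each library held 16544190.0 to 19125423 reads assigned to genes, and 13562 to 13903 genes per library reached 1 FPKM. At this depth 1 read on a gene of 1 kb was worth 0.0515 to 0.0590 FPKM. FPKM values are given as mean ± SD (n = 2 libraries per group), and log2 differences as estimate ± standard error on the log2(FPKM + 1) scale, which understates the change of low genes. List p-values are from camera, which compares a list's genes with other genes, not its mean with the spread between libraries. Parentheses after an omitted library or removed trend with gene length and GC content give a list's median and adjusted p without it.

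Control library 1 stood apart from the other 7. Its mean Spearman correlation with them across genes was 0.926, against 0.971 to 0.975 for the others, and the first principal component, with 55.1% of the variance, separated it from them. Ttr, which encodes the transthyretin secreted by the choroid plexus, was at 8778 FPKM in control library 1 and 435 in control library 2. The hemoglobin gene Hbb-bs was at 5.53 FPKM in control library 1 and at 85.2 to 212 in the other 7. The 2 libraries of each group differed by more than sampling noise, with a chi-square per degree of freedom of 64.9 in control, 10.5 in the vector group, 10.9 in the AKG group and 28.7 in the combined group. Limma pooled this spread over groups, so standard errors may be too small in comparisons with control and too large in the others.

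The vector group was compared with control to ask what the α-synuclein vector changed in mice without AKG. Genes of dopamine neurons were lower. Th, the rate-limiting enzyme of dopamine synthesis (ENSMUSG00000000214, chromosome 7, 142892752 to 142931128 in GRCm38), was at 38.8 ± 0.00404 FPKM in control and 14.4 ± 2.45 in the vector group, a log2 difference of -1.38 ± 0.13. Slc6a3, the dopamine transporter (ENSMUSG00000021609, chromosome 13, 73536747 to 73578672), was at 26.3 ± 3.13 and 2.65 ± 1.73 FPKM, a log2 difference of -2.99 ± 0.42. Ddc, which converts L-DOPA to dopamine (ENSMUSG00000020182, chromosome 11, 11814101 to 11898144), differed by -0.89 ± 0.17 and the vesicular monoamine transporter Slc18a2 (ENSMUSG00000025094, chromosome 19, 59260878 to 59296012) by -0.46 ± 0.14. None of these passed the threshold as a single gene (limma adjusted p = 0.229 for Th and 0.294 for the other 3), while all 4 were lower in both vector libraries than in both control libraries. As a list, 15 of 19 measured dopamine neuron genes were below control, with a median log2 difference of -0.45 (adjusted p = 1.26e-04, and 0.629 with an estimated correlation). Over all genes 0 passed, and 7 were lower when adjusted over the list alone. The dopamine neuron call was lost without control library 2 (-0.43, 0.0579), and the median was -0.25 without vector library 1. Markers of neighbouring regions moved the opposite way: the vector libraries had forebrain excitatory list means (log2(FPKM + 1)) of 3.86 and 4.02, against 3.48 and 3.69 in control, and thalamus and midbrain means of 3.97 and 3.87 against 3.22 and 3.83.

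**Figure D1:**
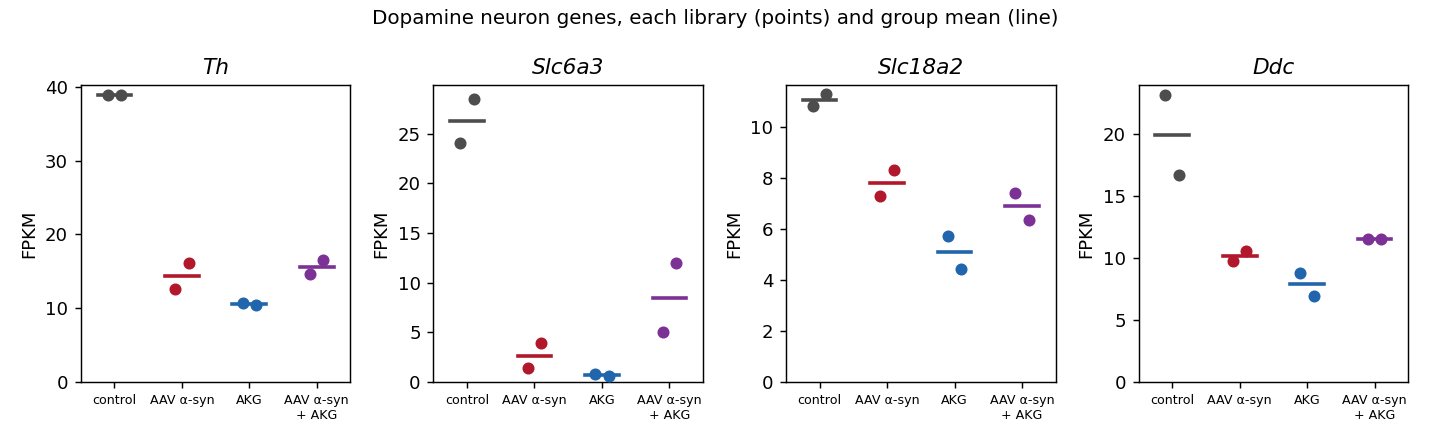
FPKM of the dopamine neuron genes Th, Slc6a3, Slc18a2 and Ddc (linear axes from 0) in the 4 groups, with points for libraries and lines for group means. Th was at 38.8 FPKM in control and at 14.4, 10.5 and 15.6 in the vector, AKG and combined groups.

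Genes for protein synthesis and respiration were also lower in the vector group than in control. Of 80 cytosolic ribosomal protein genes 78 were below control, with a median of -0.60 (adjusted p = 5.04e-20, and 0.629 with an estimated correlation). Rps27a, which encodes a ribosomal protein fused to ubiquitin, was at 169.8 ± 4.06 FPKM in control and 44.0 ± 5.57 in the vector group. Of 77 nuclear respiratory chain genes 76 were below control, with a median of -0.43 (adjusted p = 1.81e-15, and 0.629 with an estimated correlation). The complex I subunit Ndufb9 differed by -0.66 ± 0.20 and the complex III subunit Uqcrq by -0.69 ± 0.25 (limma adjusted p = 0.294 for both). In control library 1 the ribosomal list mean lay 0.77 above its mean over the 8 libraries and in control library 2 0.11 above it. The ribosomal median was -0.29 without control library 1 and -0.93 without control library 2. The respiratory chain median was -0.29 without control library 1 and -0.18 without the length and GC trend. Both stayed called. Across genes, a library's deviation from the 8-library mean correlated with gene length at Spearman rho -0.52 and -0.28 in the control, 0.26 and 0.45 in the vector and 0.44 and 0.10 in the AKG libraries, so this trend separated control from both groups. Many ribosomal protein genes have pseudogenes that could share their reads.

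Synaptic genes were higher. All 30 measured postsynaptic genes lay above control, with a median of 0.54 (adjusted p = 4.44e-11, and 0.629 with an estimated correlation). Shank1 and Shank2, scaffolds of excitatory synapses, differed by 1.24 ± 0.31 and 0.79 ± 0.19, and the NMDA receptor subunit Grin2b by 1.13 ± 0.30, each at an adjusted p of 0.294. Of 34 presynaptic genes 32 were above control, among them Bsn, a scaffold of the release site, and synapsin Syn1, with a list median of 0.34 (adjusted p = 1.76e-05, and 0.671 with an estimated correlation). The postsynaptic list mean lay -0.79 from its 8-library mean in control library 1 and -0.12 in control library 2, and the presynaptic mean -0.65 and 0.039. The postsynaptic median was 0.27 without control library 1, 0.84 without control library 2 and 0.27 without the length and GC trend, and the list stayed called. The presynaptic call was lost without control library 1 (0.026, 0.183), and the median was 0.68 without control library 2. The clock list, with the repressor Nr1d1 and the activator Hlf, was higher with a median of 0.23 in 16 of 19 genes (adjusted p = 0.00813, and 0.648 with an estimated correlation). The clock median was 0.11 without control library 1 and 0.087 without the length and GC trend.

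Some glial and immune lists were lower. The disease-associated microglia list had 17 of 18 genes below control, with a median of -0.42 (adjusted p = 2.21e-05, and 0.629 with an estimated correlation). It included the lysozyme gene Lyz2 at 19.5 ± 9.66 FPKM in control and 7.41 ± 1.87 in the vector group, the receptor adaptor Tyrobp at 27.0 ± 5.46 and 15.1 ± 3.17, and Cd68 at 6.33 ± 0.136 and 4.51 ± 0.521. Gfap, the astrocyte intermediate filament, was at 116 ± 57.3 FPKM in control and 44.8 ± 0.755 in the vector group, and 21 of 23 reactive astrocyte genes were below control with a median of -0.28 (adjusted p = 7.66e-04, and 0.671 with an estimated correlation). The complement list, led by C1qa, C1qb and C1qc, had a median of -0.36 in 10 genes (adjusted p = 0.00905, and 0.629 with an estimated correlation), and 4 of them were lower adjusted over the list alone. The disease-associated microglia list mean lay 0.57 above its 8-library mean in control library 1 and the reactive astrocyte mean 0.57 above. The reactive astrocyte (-0.036, 0.554) and complement (-0.038, 0.258) calls were lost without control library 1. The disease-associated microglia median was then -0.27. Without control library 2 the medians were -0.57 (reactive astrocyte), -0.67 (complement) and -0.75 (disease-associated microglia).

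Some lists of stress and antigen presentation genes were lower as well. With an estimated correlation the lists named next had an adjusted p of 0.629, except for 0.806 in choroid plexus genes. NRF2 and oxidative stress genes, among them Sod1, Prdx1 and Hmox1, had a median of -0.32 in 31 genes (adjusted p = 1.60e-04). The MHC class I list with H2-K1 and Psmb10 had a median of -0.34 (adjusted p = 8.79e-04), and the interferon response list with Ifit3 one of -0.39 (adjusted p = 9.36e-04). The lysosome list, with the proteases Ctss and Ctsz, had a median of -0.15 in 42 genes (adjusted p = 0.00813). The MHC class I call was lost without vector library 1 (-0.23, 0.0603), and the median was -0.17 without control library 1. The interferon call was lost without vector library 1 (-0.35, 0.0678), and the median was -0.19 without control library 1. The NRF2 median was -0.12 without control library 1, -0.54 without control library 2 and -0.14 without the length and GC trend. The lysosome median was -0.10 without the length and GC trend. The choroid plexus and ependyma list had a median of -0.88 (adjusted p = 0.0111). The choroid plexus call was lost without control library 1 (0.30, 0.126) or vector library 1 (-0.21, 0.217), and the median was -1.88 without control library 2 and -1.34 without vector library 2. The dioxygenases that use AKG as a co-substrate, such as the histone demethylase Kdm6b and the DNA demethylase Tet3, had a median of 0.10 in 40 genes (adjusted p = 0.0271). The dioxygenase call was lost without control library 2 (0.11, 0.126) or the length and GC trend (0.0042, 0.907), and the median was 0.19 without vector library 1. The forebrain excitatory neuron list had a median of 0.40 (adjusted p = 0.0180). The forebrain excitatory call was lost without control library 2 (0.50, 0.0597).

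With an estimated correlation the next 5 lists had an adjusted p of 0.629, except for 0.671 in thalamus and microglia genes. The thalamus and midbrain excitatory neuron list, with Prkcd and Rora, had a median of 0.36 (adjusted p = 0.0419). The thalamus and midbrain call was lost without control library 1 (0.076, 0.0654), vector library 1 (0.25, 0.0694), AKG library 1 (0.36, 0.0943), AKG library 2 (0.36, 0.0935), combined library 1 (0.36, 0.0567) or combined library 2 (0.36, 0.0566), and the median was 0.63 without control library 2. The oligodendrocyte precursor list had a median of 0.20 (adjusted p = 0.0419). The oligodendrocyte precursor call was lost without control library 1 (0.084, 0.128), control library 2 (0.24, 0.0724), vector library 1 (0.21, 0.136), AKG library 1 (0.20, 0.0642), AKG library 2 (0.20, 0.0646) or the length and GC trend (0.0051, 0.850). The unfolded protein response list, with Xbp1, had a median of -0.21 (adjusted p = 0.0377). The unfolded protein response call was lost without control library 1 (-0.11, 0.115), vector library 2 (-0.17, 0.0717) or the length and GC trend (-0.072, 0.214). The homeostatic microglia list, with Tmem119, had a median of -0.20 (adjusted p = 0.0377). The homeostatic microglia call was lost without control library 2 (-0.12, 0.188), vector library 2 (-0.10, 0.175) or the length and GC trend (-0.10, 0.301). The MHC class II list, with H2-Ab1, had a median of -0.56 in 8 genes (adjusted p = 0.0326). The MHC class II call was lost without control library 1 (-0.14, 0.439), vector library 1 (-0.19, 0.208) or the length and GC trend (-0.27, 0.372), and the median was -1.02 without control library 2.

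Of 13716 single genes tested in this comparison, limma called 0 at an adjusted p under 0.05, and voom on the recovered reads also called 0. At an unadjusted p under 0.05 there were 2305, where chance gives 686 in each of the 7 comparisons. The count was 1566 with library weights and 1232 with only the groups compared. It was also lower without control library 1, which stood apart, so the excess cannot be credited to the vector. Besides Th and Slc6a3, the genes with the smallest unadjusted p below control were Rpa3 (-0.68 ± 0.11), Polr2j (-0.56 ± 0.10) and Mir1968. Above control they were Wnk2 (0.99 ± 0.18), the intracellular calcium channel Itpr1 (0.71 ± 0.14), Hr (0.95 ± 0.18), Mir149 and Snord73a, all with an adjusted p of 0.294. Mir149 and Snord73a were listed at 0 in both control libraries and Mir1968 in both vector libraries, and these very short genes lie inside Gpc1, Rps3a1 and Grtp1. The ribosomal, respiratory chain, postsynaptic, clock, disease-associated microglia, NRF2 and lysosome lists kept their call in all 8 fits without a single library.

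The AKG group was compared with control to ask what AKG changed in mice whose label names no vector. Th was the 1 gene called, lower in the AKG group at 10.5 ± 0.254 FPKM than in control at 38.8 ± 0.00404, a log2 difference of -1.79 ± 0.13 (limma adjusted p = 0.0414, lower in 2 of 2 libraries). Slc6a3 was at 0.708 ± 0.132 FPKM in the AKG group and 26.3 ± 3.13 in control, with a log2 difference of -4.00 ± 0.42 that missed the threshold (adjusted p = 0.199). Ddc (-1.23 ± 0.17) and Slc18a2 (-0.997 ± 0.14) also missed it (adjusted p = 0.269 for both). Of 19 dopamine neuron genes 15 were below control, with a median of -0.37 (adjusted p = 1.7e-05, and 0.671 with an estimated correlation). Adjusted over the list alone 7 were lower, against 1 over all genes, and the list kept its call without any single library. The forebrain and thalamus means were again higher, at 3.86 and 4.12 and at 3.99 and 4.21. Th was called in 9 of 20 alternative settings, with adjusted p from 0.00349 to 0.738. Its call held without control library 2 and was lost without any of the other 7 libraries, while its log2 difference stayed between -1.81 and -1.77.

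Lists outside the dopamine neurons were also called in the AKG group, each with an adjusted p of 0.671 with an estimated correlation. Ribosomal protein genes had a median of -0.62 in 80 genes, 78 of them below control (adjusted p = 5.15e-21). Respiratory chain genes had one of -0.39, 75 of 77 below control (adjusted p = 3.34e-13), with the complex I subunits Ndufc2 at -0.62 ± 0.19 and Ndufa11 at -0.58 ± 0.19. Postsynaptic genes had a median of 0.60, 29 of 30 above control (adjusted p = 2.33e-10), and 16 of them were higher adjusted over the list alone. Shank1 differed by 1.42 ± 0.31 and Grin2b by 1.30 ± 0.30 (limma adjusted p = 0.269 for both). MHC class I genes were all 15 below control with a median of -0.43 (adjusted p = 7.57e-05), as were all 18 disease-associated microglia genes with a median of -0.40 (adjusted p = 1.44e-04). NRF2 genes, such as Prdx1 and Gstm1, had a median of -0.32 (adjusted p = 3.12e-04). These 6 lists and the dopamine neuron list were called the same way in all 8 fits that left out 1 library. Without control library 1 the medians were -0.29 (ribosomal), -0.26 (respiratory chain), 0.28 (postsynaptic), -0.16 (disease-associated microglia) and -0.13 (NRF2). Without control library 2 they were -0.95 (ribosomal), -0.64 (disease-associated microglia) and -0.52 (NRF2). Without the length and GC trend they were -0.17 (respiratory chain), 0.32 (postsynaptic), -0.23 (disease-associated microglia), -0.17 (NRF2) and -0.27 (MHC class I). The respiratory chain median was -0.24 without AKG library 1.

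The remaining calls of this comparison depended on single libraries, each with an adjusted p of 0.671 with an estimated correlation. The presynaptic list had a median of 0.37 (adjusted p = 1.65e-05), lost without control library 1 (0.012, 0.146), and at 0.71 without control library 2. The reactive astrocyte list had a median of -0.38 (adjusted p = 3.59e-04), lost without control library 1 (-0.054, 0.523), and at -0.58 without control library 2. Gfap was at 42.7 ± 4.15 FPKM in the AKG group, a log2 difference of -1.33 ± 0.31 from control. The thalamus and midbrain excitatory list, with Prkcd at 29.99 ± 21.3 FPKM in control and 94.3 ± 3.99 in the AKG group, had a median of 0.51 (adjusted p = 0.00769), lost without AKG library 2 (0.45, 0.246). The forebrain excitatory list, with Camk2a and Slc17a7, had a median of 0.53 (adjusted p = 0.0197), lost without control library 2 (0.56, 0.0541) or AKG library 2 (0.37, 0.0994), and at 0.30 without control library 1. The clock list had a median of 0.24 (adjusted p = 0.00587), lost without AKG library 1 (0.13, 0.0567) or the length and GC trend (0.085, 0.0628), and at 0.14 without control library 1. Complement genes had a median of -0.34 (adjusted p = 0.0275), lost without control library 1 (-0.071, 0.734) or AKG library 1 (-0.29, 0.0567), and at -0.64 without control library 2. The interferon list had a median of -0.27 (adjusted p = 0.0317), lost without control library 1 (-0.053, 0.365), AKG library 1 (-0.11, 0.277) or the length and GC trend (-0.18, 0.216). Homeostatic microglia genes had a median of -0.15 (adjusted p = 0.0462), lost without control library 2 (-0.16, 0.188), AKG library 1 (-0.082, 0.180) or the length and GC trend (-0.076, 0.479), and at -0.25 without AKG library 2.

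Lists close to AKG metabolism had small medians. The TCA cycle and AKG metabolism list, led by the succinate dehydrogenase subunit Sdhb (-0.43 ± 0.18) and the serine synthesis enzyme Phgdh (-0.46 ± 0.17), had a median of -0.10 in 40 genes (adjusted p = 0.0462, and 0.694 with an estimated correlation), lost without control library 2 (-0.082, 0.215), vector library 1 (-0.10, 0.0521), vector library 2 (-0.10, 0.0522), AKG library 1 (-0.075, 0.173) or the length and GC trend (-0.064, 0.161). The AKG-dependent dioxygenases, led by Kdm6b (0.68 ± 0.14) and Kdm7a (0.67 ± 0.17), had a median of 0.10 (adjusted p = 0.0462, and 0.671 with an estimated correlation), lost without control library 1 (0.093, 0.0695), control library 2 (0.065, 0.169), vector library 1 (0.10, 0.0509), vector library 2 (0.10, 0.0513), AKG library 1 (0.070, 0.127) or the length and GC trend (-0.021, 0.988). The lysosome list had a median of -0.11 (adjusted p = 0.0462, and 0.671 with an estimated correlation), lost without control library 1 (-0.083, 0.0970), control library 2 (-0.12, 0.0854), AKG library 1 (-0.10, 0.162) or the length and GC trend (-0.11, 0.123). Oligodendrocyte precursor genes had one of 0.18 (adjusted p = 0.0417, and 0.671 with an estimated correlation), lost without control library 1 (0.0075, 0.163), control library 2 (0.26, 0.0541), AKG library 2 (0.18, 0.137) or the length and GC trend (0.041, 0.696). Cholinergic and motor neuron genes had one of -0.37 in 8 genes (adjusted p = 0.0462, and 0.671 with an estimated correlation), lost without control library 1 (-0.31, 0.146), control library 2 (-0.44, 0.0669), AKG library 1 (-0.33, 0.0662) or the length and GC trend (-0.41, 0.107).

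At an unadjusted p under 0.05 there were 2431 genes in the comparison of AKG with control. This count was 1704 with library weights and 1178 with only the groups compared, and again lower without control library 1. Voom called 1 gene, which was Th. Genes that missed the threshold with the smallest unadjusted p were the mitochondrial transfer RNAs mt-Tl2 (1.61 ± 0.21) and mt-Ts2 (1.01 ± 0.13), Itpr1 (0.86 ± 0.14), Peak1 (0.87 ± 0.15) and Mir149 above control, and Srp54b (-1.54 ± 0.18) below it with Slc6a3, Ddc and Slc18a2. The 2 transfer RNAs are very short and overlap, and Srp54b has near-identical copies. Across genes, the differences of the vector group and of the AKG group from control correlated with Pearson r 0.869 and Spearman rho 0.888. Both differences use the same control libraries, and unchanged groups set against them gave a simulated r of 0.775 (0.717 to 0.807). The covariance was 0.105 against a simulated 0.0580, and the excess of 0.0472 was smaller than its jackknife standard error of 0.170. Part of the excess may come from the shared controls, which are too few to split, and genes are not independent replicates.

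**Figure D2:**
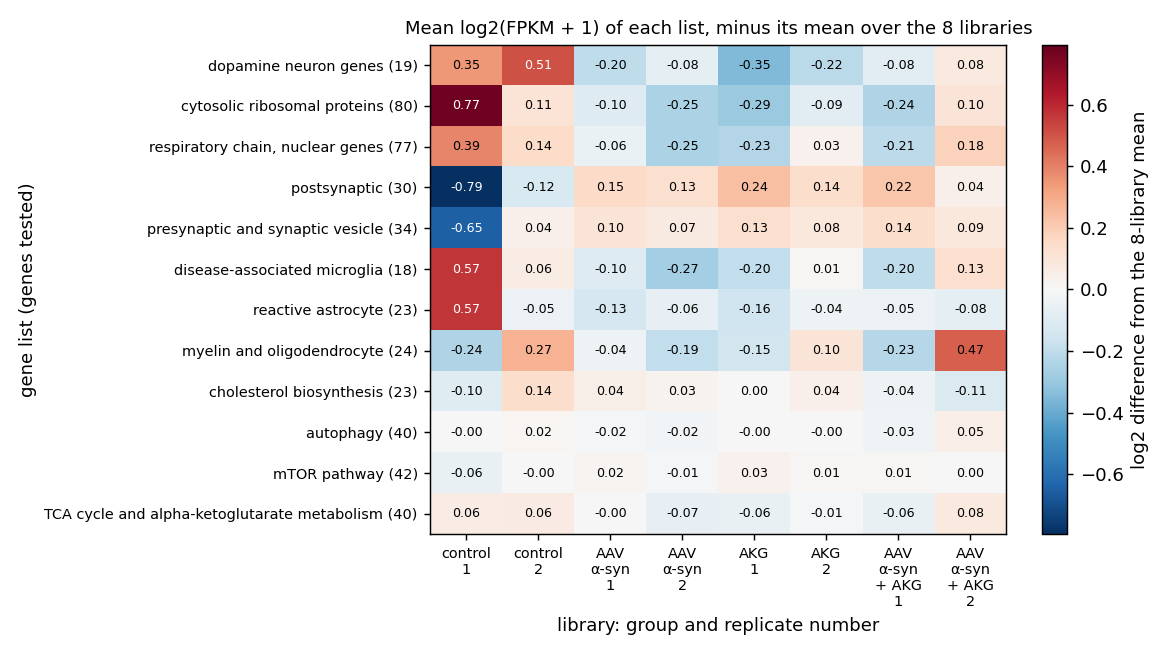
Mean log2(FPKM + 1) of 12 gene lists in each library, minus the list's mean over the 8 libraries (color scale in log2 units, red above and blue below the mean). Dopamine neuron genes lay 0.35 and 0.51 above the mean in the control libraries, while the ribosomal mean lay 0.77 above in control library 1 and 0.11 in control library 2.

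The combined group was compared with the vector group to ask what AKG changed in mice given the vector. Each list called had an adjusted p of 0.976 with an estimated correlation. Cholesterol biosynthesis genes were lower in the combined group, 22 of 23 with a median of -0.12 (adjusted p = 1.88e-05). Msmo1, a sterol demethylation enzyme, was at 16.9 ± 0.495 FPKM in the vector group and 13.7 ± 1.48 in the combined group, and squalene synthase Fdft1 at 29.9 ± 0.0340 and 26.3 ± 0.411. This list alone was called the same way in all 8 fits without a single library. The cholesterol median was -0.067 without combined library 2. Myelin and oligodendrocyte genes were higher, 23 of 24 with a median of 0.24 (adjusted p = 1.28e-04), among them Mobp at 181 ± 27.7 and 219 ± 47.6 FPKM and Mal at 123 ± 10.8 and 146 ± 20.1. In the combined group the myelin list mean lay -0.23 from its 8-library mean in library 1 and 0.47 in library 2. The myelin call was lost without vector library 2 (0.11, 0.134) or combined library 2 (-0.036, 0.454), and the median was 0.59 without combined library 1. Respiratory chain genes had a median of 0.11 (adjusted p = 3.42e-06) and ribosomal protein genes one of 0.11 (adjusted p = 0.0172). The respiratory chain call was lost without vector library 2 (0.036, 0.267) and called in the opposite direction without combined library 2 (-0.052, 0.0249), and the median was 0.20 without vector library 1 and 0.32 without combined library 1. The ribosomal call was lost without vector library 2 (0.038, 0.6003) or combined library 2 (-0.060, 0.162), and the median was 0.17 without vector library 1, 0.28 without combined library 1 and 0.054 without the length and GC trend.

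Some microglial, immune and vascular lists were higher in the combined than in the vector group. The complement list, with C1qa at 51.1 ± 6.84 and 67.4 ± 10.8 FPKM, had a median of 0.17 (adjusted p = 0.0133). The complement call was lost without vector library 2 (0.20, 0.165) or combined library 1 (0.20, 0.159). The disease-associated microglia list, with Cd68 at 4.51 ± 0.521 and 5.79 ± 1.24 FPKM, had a median of 0.21 (adjusted p = 0.0101). The disease-associated microglia call was lost without vector library 2 (0.11, 0.284) or combined library 2 (0.036, 0.965), and the median was 0.38 without combined library 1. Homeostatic microglia genes had a median of 0.11 (adjusted p = 0.0224). The homeostatic microglia call was lost without vector library 2 (0.031, 0.428) or combined library 2 (-0.0042, 0.806), and the median was 0.20 without vector library 1 and 0.20 without combined library 1. The interferon list had a median of 0.17 (adjusted p = 0.0439). The interferon call was lost without vector library 1 (0.11, 0.915) or combined library 2 (0.055, 0.565), and the median was 0.28 without vector library 2 and 0.11 without the length and GC trend. Endothelial genes, with Ly6c1 at 35.4 ± 1.09 and 49.5 ± 5.23 FPKM and Ly6a at 32.6 ± 1.10 and 45.6 ± 2.61, had a median of 0.12 (adjusted p = 0.00116). The endothelial call was lost without combined library 2 (0.037, 0.341). Dopamine neuron genes had a median of 0.094 in the combined group against the vector group and were not called (camera adjusted p = 0.268). Th was at 15.6 ± 1.41 FPKM against 14.4 ± 2.45 (0.12 ± 0.13), Slc6a3 at 8.46 ± 4.92 against 2.65 ± 1.73 (1.36 ± 0.42) and Slc18a2 at 6.88 ± 0.743 against 7.79 ± 0.724, each with an adjusted p of 0.99996. Limma and voom each called 0 single genes here, and 186 (297 with only the groups compared) reached an unadjusted p under 0.05. Those with the smallest unadjusted p included Rpl21 (1.07 ± 0.29), Adap2 (0.53 ± 0.15), Alb (-0.91 ± 0.17) and C1ql4 (-0.67 ± 0.18).

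The combined group was compared with the AKG group to ask what the vector changed in mice on AKG. Dopamine neuron genes were higher in the combined group, 15 of 19 with a median of 0.063 and a mean of 0.28 (adjusted p = 2.53e-04, and 0.844 with an estimated correlation). The dopamine neuron call was lost without AKG library 1 (0.021, 0.0896), and the median was 0.23 without AKG library 2, 0.14 without combined library 1 and 0.12 without combined library 2. Slc6a3 was at 8.46 ± 4.92 FPKM in the combined group and 0.708 ± 0.132 in the AKG group, a log2 difference of 2.37 ± 0.42, Th at 15.6 ± 1.41 and 10.5 ± 0.254 (0.52 ± 0.13) and Slc10a4, a vesicle protein of monoamine and cholinergic neurons, at 3.36 ± 2.12 and 1.02 ± 0.0534. These 3 missed the threshold over all genes (limma adjusted p = 0.9999), and 1 was higher adjusted over the list alone. Cholesterol biosynthesis genes were lower, 20 of 23 with a median of -0.10 (adjusted p = 4.33e-04, and 0.951 with an estimated correlation). The cholesterol call was lost without AKG library 2 (-0.062, 0.0834) or combined library 2 (-0.048, 0.227). The glucocorticoid response list, with Tsc22d3, Nfkbia and Per1, had a median of 0.21 (adjusted p = 0.00185, and 0.951 with an estimated correlation). The glucocorticoid call was lost without AKG library 1 (0.21, 0.0823) or combined library 1 (0.069, 0.996), and the median was 0.36 without combined library 2. GABA neuron genes, with Gad1 at 47.5 ± 12.2 and 35.4 ± 4.24 FPKM, had a median of 0.18 (adjusted p = 0.0127, and 0.951 with an estimated correlation). The GABA neuron call was lost without AKG library 2 (-0.021, 0.885) or combined library 2 (0.13, 0.529), and the median was 0.27 without AKG library 1 and 0.28 without combined library 1.

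The other 8 calls of this comparison each depended on at least 1 library and had an adjusted p of 0.951 with an estimated correlation. Respiratory chain genes had a median of 0.082 (adjusted p = 2.53e-04), lost without AKG library 1 (-0.024, 0.521) and called in the opposite direction without combined library 2 (-0.10, 0.00116), and at 0.20 without AKG library 2 and 0.28 without combined library 1. Ribosomal protein genes had one of 0.12 (adjusted p = 3.90e-04), lost without AKG library 1 (0.028, 0.803) or combined library 2 (-0.050, 0.428), and at 0.21 without AKG library 2 and 0.29 without combined library 1. Myelin genes had one of 0.19 (adjusted p = 4.33e-04), lost without AKG library 1 (0.11, 0.521) or combined library 2 (-0.10, 0.342), and at 0.31 without AKG library 2 and 0.49 without combined library 1. Endothelial genes had one of 0.078 (adjusted p = 0.00291), lost without AKG library 1 (-0.0096, 0.803) or combined library 2 (0.0073, 0.617), and at 0.16 without AKG library 2 and 0.14 without combined library 1. Homeostatic microglia genes had one of 0.094 (adjusted p = 0.0126), lost without AKG library 1 (0.032, 0.531) or combined library 2 (-0.042, 0.720), and at 0.20 without combined library 1. The choroid plexus and ependyma list had one of -0.48 (adjusted p = 0.00448), lost without AKG library 2 (-0.26, 0.364) or combined library 1 (0.61, 0.859), and at -0.79 without combined library 2. Heat shock and chaperone genes, with Hsph1, had one of -0.091 (adjusted p = 0.0204), lost without AKG library 2 (-0.049, 0.216), combined library 1 (-0.049, 0.250) or combined library 2 (-0.12, 0.115). Thalamus and midbrain excitatory genes, with Zic1, had one of -0.16 (adjusted p = 0.0367), lost without AKG library 2 (-0.066, 0.856), combined library 1 (-0.17, 0.321) or combined library 2 (-0.18, 0.227). Limma and voom each called 0 single genes, and 156 reached an unadjusted p under 0.05.

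The interaction asks whether the effect of the vector differed with AKG. For Th it was 1.90 ± 0.19 on the log2 scale, for Slc6a3 5.35 ± 0.59, for Ddc 1.40 ± 0.24 and for Slc10a4 2.42 ± 0.44, with an adjusted p of 0.276, 0.283, 0.537 and 0.537, so none passed. Limma and voom each called 0 genes, and 998 reached an unadjusted p under 0.05. The dopamine neuron list had an interaction median of 0.47 (adjusted p = 9.98e-06, and 0.618 with an estimated correlation), and 6 genes passed adjusted over the list alone. Camera called 19 of 43 lists, 13 with positive and 6 with negative medians, and all lost their call with an estimated correlation (adjusted p = 0.618 to 0.786). They included the ribosomal protein genes at 0.73, disease-associated microglia genes at 0.57, postsynaptic genes at -0.55 and respiratory chain genes at 0.51. These 4, the dopamine neuron list and the NRF2 list kept their call in all 8 fits without a single library. Without control library 1 the medians were 0.42 (ribosomal), 0.36 (disease-associated microglia), -0.29 (postsynaptic) and 0.18 (NRF2). Without control library 2 they were -0.84 (postsynaptic) and 0.66 (NRF2). Without the length and GC trend they were -0.27 (postsynaptic), 0.26 (respiratory chain) and 0.21 (NRF2). Without combined library 2 they were 0.32 (respiratory chain) and 0.26 (NRF2). The dopamine neuron median was 0.30 without AKG library 1.

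Of the other 13 interaction calls, which each depended on at least 1 library, 7 were of presynaptic, astrocyte, microglia, immune and lysosome lists. These 7 had an adjusted p of 0.676 with an estimated correlation, except for 0.714 in presynaptic genes. Presynaptic genes were at -0.35 (adjusted p = 3.12e-04), lost without control library 1 (-0.072, 0.333), and at -0.66 without control library 2. Reactive astrocyte genes were at 0.34 (adjusted p = 0.00222), lost without control library 1 (0.063, 0.443), and at 0.51 without control library 2. Complement genes were at 0.56 (adjusted p = 0.00339), lost without control library 1 (0.13, 0.0808), and at 0.87 without control library 2. MHC class I genes were at 0.39 (adjusted p = 0.00184), lost without vector library 1 (0.25, 0.0644), and at 0.16 without control library 1 and 0.23 without AKG library 1. Interferon response genes were at 0.36 (adjusted p = 0.00521), lost without vector library 1 (0.29, 0.131), and at 0.55 without vector library 2, 0.21 without AKG library 1 and 0.54 without AKG library 2. Homeostatic microglia genes were at 0.28 (adjusted p = 0.00497), lost without combined library 2 (0.17, 0.0771) or the length and GC trend (0.23, 0.0506). Lysosome genes were at 0.14 (adjusted p = 0.0169), lost without combined library 2 (0.10, 0.190), and at 0.22 without combined library 1.

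The other 6 were of the oligodendrocyte lineage, excitatory neurons and AKG metabolism, with an adjusted p of 0.676 with an estimated correlation, except for 0.786 in myelin genes. Myelin genes were at 0.32 (adjusted p = 0.0249), lost without control library 2 (0.18, 0.990), vector library 2 (0.19, 0.128), AKG library 1 (0.18, 0.158), combined library 2 (0.038, 0.740) or the length and GC trend (0.24, 0.0874), and at 0.60 without control library 1 and 0.61 without combined library 1. Oligodendrocyte precursor genes were at -0.25 (adjusted p = 0.0383), lost without control library 1 (-0.041, 0.166), control library 2 (-0.27, 0.0525), vector library 1 (-0.23, 0.104), AKG library 2 (-0.21, 0.137), combined library 2 (-0.21, 0.0681) or the length and GC trend (-0.0047, 0.658). Thalamus and midbrain excitatory genes were at -0.51 (adjusted p = 0.01003), lost without AKG library 2 (-0.54, 0.258) or combined library 1 (-0.49, 0.0509), and at -0.32 without control library 1. Forebrain excitatory genes were at -0.49 (adjusted p = 0.0481), lost without control library 2 (-0.58, 0.0734), vector library 2 (-0.32, 0.115), AKG library 2 (-0.27, 0.258) or combined library 2 (-0.23, 0.241). TCA cycle and AKG metabolism genes were at 0.12 (adjusted p = 0.0257), lost without control library 2 (0.10, 0.138), vector library 2 (0.088, 0.0986), AKG library 1 (0.10, 0.0768), combined library 2 (0.061, 0.192) or the length and GC trend (0.12, 0.0630), and at 0.23 without combined library 1. AKG-dependent dioxygenases were at -0.13 (adjusted p = 0.0241), lost without control library 2 (-0.093, 0.0973), combined library 2 (-0.091, 0.0613) or the length and GC trend (-0.0056, 0.716).

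Across genes, the effect of the vector without AKG and its effect with AKG, which share no library, correlated with Pearson r -0.121 (jackknife standard error 0.512) and Spearman rho -0.196. Unchanged groups gave simulated values of r from -0.344 to 0.344, so the observed value lay within them. The effect of the vector and the effect of AKG in mice given the vector correlated with r -0.359 and rho -0.348. These 2 effects share the vector libraries with opposite signs, and unchanged groups gave a simulated r of -0.284 (-0.548 to 0.0126). With each library left out in turn the first r ran from -0.400 to 0.243.

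Averaged over mice with and without AKG, the vector libraries had ribosomal protein genes at a median of -0.25 (adjusted p = 4.13e-14), respiratory chain genes at -0.17 (adjusted p = 1.71e-09), postsynaptic genes at 0.25 (adjusted p = 1.71e-09) and clock genes at 0.13 (adjusted p = 0.00120). All 4 had an adjusted p = 0.662 with an estimated correlation. These 4 of 18 called lists kept their call in all 8 fits without a single library. Without control library 1 the medians were -0.086 (ribosomal), -0.10 (respiratory chain) and 0.080 (postsynaptic), and without control library 2 -0.41 (ribosomal) and 0.40 (postsynaptic). Without the length and GC trend they were -0.16 (ribosomal), -0.074 (respiratory chain), 0.14 (postsynaptic) and 0.078 (clock). The respiratory chain median was -0.11 without vector library 2, -0.10 without AKG library 2, -0.063 without combined library 1 and -0.26 without combined library 2. The dopamine neuron list had a median of -0.17 (adjusted p = 0.0116, and 0.662 with an estimated correlation), but was called higher in mice on AKG (0.063). The dopamine neuron call was lost without control library 2 (-0.13, 0.243) or vector library 1 (-0.079, 0.0577), and the median was -0.10 without AKG library 2 and -0.087 without combined library 1. Averaged over mice with and without the vector, the AKG libraries had ribosomal genes at -0.25 (adjusted p = 6.53e-15), postsynaptic genes at 0.27 (adjusted p = 1.92e-08), clock genes at 0.13 (adjusted p = 7.71e-04), MHC class I genes at -0.19 (adjusted p = 6.21e-05) and dopamine neuron genes at -0.17 (adjusted p = 3.58e-05, and 0.764 with an estimated correlation). The other 4 had an adjusted p = 0.873 with an estimated correlation. These 5 of 13 called lists kept their call in all 8 such fits. Without control library 1 the medians were -0.10 (ribosomal), 0.15 (postsynaptic), 0.068 (clock) and -0.090 (MHC class I). Without control library 2 they were -0.41 (ribosomal), 0.42 (postsynaptic) and -0.29 (MHC class I). The postsynaptic median was 0.14 without the length and GC trend. The dopamine neuron median was -0.11 without AKG library 1 and -0.31 without combined library 1. With AKG in mice given the vector, ribosomal genes (0.11) were instead called higher, as were respiratory chain (0.11) and disease-associated microglia genes (0.21). Th had an average difference of -0.43 ± 0.094 for the vector (adjusted p = 0.724) and -0.84 ± 0.094 for AKG (adjusted p = 0.373). Limma and voom each called 0 genes for either average, and 545 and 904 reached an unadjusted p under 0.05.

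The remaining lists called for the average effect of the vector had these medians, each with the same adjusted p of 0.662 with an estimated correlation. Disease-associated microglia genes were at -0.21 (adjusted p = 0.00112), lost without control library 1 (-0.068, 0.0984), and at -0.33 without control library 2 and -0.13 without combined library 1. Reactive astrocyte genes were at -0.15 (adjusted p = 0.00219), lost without control library 1 (-0.0081, 0.926), and at -0.26 without control library 2 and -0.082 without vector library 1. Interferon genes were at -0.22 (adjusted p = 0.00112), lost without vector library 1 (-0.20, 0.0819), and at -0.12 without control library 1 and -0.13 without AKG library 2. MHC class I genes were at -0.15 (adjusted p = 0.00349), lost without control library 1 (-0.092, 0.184) or vector library 1 (-0.082, 0.155), and at -0.10 without combined library 1 and -0.089 without the length and GC trend. MHC class II genes were at -0.24 (adjusted p = 0.0246), lost without control library 1 (-0.067, 0.415), vector library 1 (-0.092, 0.177), AKG library 2 (-0.15, 0.0652), combined library 1 (-0.13, 0.0727) or the length and GC trend (-0.11, 0.301), and at -0.51 without control library 2, -0.42 without vector library 2 and -0.39 without combined library 2. Choroid plexus genes were at -0.63 (adjusted p = 3.00e-04), lost without control library 1 (-0.11, 0.362), and at -1.20 without control library 2 and -0.32 without combined library 1. Forebrain excitatory genes were at 0.17 (adjusted p = 0.0119), lost without AKG library 1 (0.19, 0.0746) or combined library 1 (0.16, 0.0965), and at 0.28 without AKG library 2 and 0.28 without combined library 2. Lysosome genes were at -0.078 (adjusted p = 0.0136), lost without control library 2 (-0.10, 0.0509) or combined library 1 (-0.022, 0.216), and at -0.049 without control library 1 and -0.037 without the length and GC trend. Presynaptic genes were at 0.19 (adjusted p = 2.99e-05), lost without control library 1 (0.014, 0.221), and at 0.35 without control library 2. Immediate early genes were at 0.13 (adjusted p = 0.0291), lost without control library 2 (0.15, 0.182), vector library 1 (0.12, 0.0938), AKG library 1 (0.12, 0.0719) or combined library 2 (0.13, 0.0708), and at 0.057 without control library 1, 0.075 without combined library 1 and 0.19 without the length and GC trend. Unfolded protein response genes were at -0.064 (adjusted p = 0.0144), lost without control library 1 (-0.069, 0.0531) or the length and GC trend (-0.050, 0.0647), and at -0.12 without control library 2, -0.10 without vector library 1 and -0.12 without combined library 2. Heat shock genes were at -0.062 (adjusted p = 0.0205), lost without control library 2 (-0.056, 0.295), vector library 2 (-0.022, 0.195) or combined library 2 (-0.060, 0.0542), and at -0.11 without control library 1 and -0.13 without vector library 1. NRF2 genes were at -0.14 (adjusted p = 0.00112), lost without control library 1 (-0.041, 0.184), and at -0.22 without control library 2, -0.083 without combined library 1 and -0.077 without the length and GC trend.

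The remaining lists called for the average effect of AKG had these medians, each with the same adjusted p of 0.873 with an estimated correlation. Disease-associated microglia genes were at -0.11 (adjusted p = 0.0395), lost without control library 1 (-0.0063, 0.872), vector library 1 (-0.10, 0.192), AKG library 1 (-0.094, 0.320), combined library 1 (-0.018, 0.578) or the length and GC trend (-0.073, 0.479), and at -0.24 without control library 2. Reactive astrocyte genes were at -0.14 (adjusted p = 0.00130), lost without control library 1 (-0.0023, 0.843), and at -0.29 without control library 2. Forebrain excitatory genes were at 0.28 (adjusted p = 0.0150), lost without AKG library 2 (0.11, 0.0678) or combined library 1 (0.036, 0.228), and at 0.14 without control library 1 and 0.13 without vector library 1. Thalamus and midbrain genes were at 0.27 (adjusted p = 0.0125), lost without AKG library 2 (0.20, 0.277), and at 0.41 without control library 2. Respiratory chain genes were at -0.12 (adjusted p = 1.19e-05), lost without combined library 1 (-0.027, 0.400) or the length and GC trend (-0.044, 0.0977), and at -0.058 without control library 1, -0.18 without control library 2, -0.051 without vector library 1, -0.049 without AKG library 1, -0.18 without AKG library 2 and -0.21 without combined library 2. Cholesterol genes were at -0.062 (adjusted p = 0.0155), lost without control library 2 (-0.0091, 0.668), AKG library 1 (-0.035, 0.0515) or combined library 2 (-0.056, 0.106), and at -0.13 without control library 1. Presynaptic genes were at 0.21 (adjusted p = 3.47e-05), lost without control library 1 (0.022, 0.177), and at 0.38 without control library 2 and 0.12 without the length and GC trend. NRF2 genes were at -0.10 (adjusted p = 0.00561), lost without control library 1 (-0.0092, 0.350), combined library 1 (-0.045, 0.170) or the length and GC trend (-0.074, 0.0926), and at -0.17 without control library 2 and -0.16 without combined library 2.

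Genes of autophagy and growth signalling were not called as lists, with members that went both ways. The autophagy list had medians from -0.055 to 0.025 over the 7 comparisons and the mTOR pathway list from -0.069 to 0.0077 (camera adjusted p = 0.685 to 0.955 and 0.459 to 0.917). The autophagy receptor Sqstm1 was at 239.9 ± 5.14 FPKM in control, 199.6 ± 6.22 in the vector group, 199 ± 3.06 in the AKG group and 205 ± 11.9 in the combined group. Map1lc3b, which encodes the autophagosome protein LC3B, was at 32.8, 30.5, 30.1 and 30.3 FPKM, and the mTORC1 activator Rheb at 20.3, 17.2, 17.0 and 17.7. Sqstm1 (195 to 214 against 236 and 244 FPKM) and Rheb (16.6 to 17.9 against 19.7 and 20.97 FPKM) were lower in all 6 other libraries than in both control libraries. Ogdh, a subunit of the enzyme that consumes AKG, was at 47.2 ± 9.28 FPKM in control and 57.0 ± 1.47 in the AKG group, and Idh1, which makes AKG from isocitrate, at 23.3 ± 1.96 and 20.8 ± 1.18. The microglial marker Aif1 was at 3.60 ± 0.829 FPKM in control and 2.48 ± 0.791 in the vector group. None of these 6 genes passed the threshold in any of the 7 comparisons, with the lowest adjusted p at 0.270 for Rheb in AKG against control. Polyunsaturated fatty acid metabolism (-0.025 to 0.018), Parkinson disease genes (-0.032 to 0.050), apoptosis and p53 genes (-0.063 to 0.075) and astrocyte identity genes (-0.043 to 0.023) were likewise called in no comparison.

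**Figure D3:**
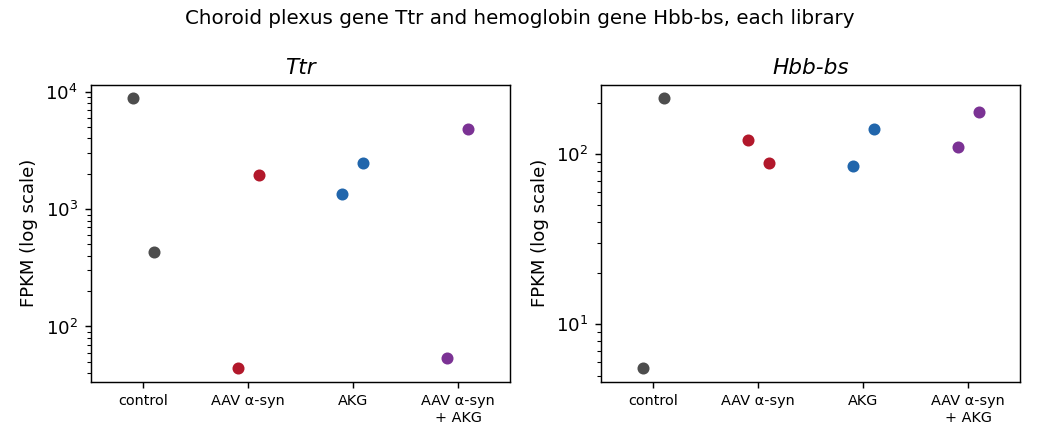
FPKM (log axes) of the choroid plexus gene Ttr and the hemoglobin gene Hbb-bs, with a point for each of the 8 libraries in the 4 groups. Ttr ranged from 44.0 to 8778 FPKM, and Hbb-bs was lowest, at 5.53, in the control library with the highest Ttr.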

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

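The tests of the vector alone, of exchanged labels, of control library 1 and of the length and GC trend were chosen only after the result was seen, while the tests of neighbouring regions and of other splits of the libraries were set beforehand. For 19 gene lists the vector's effect differed between mice without and with AKG by the interaction (camera, adjusted over 43 lists, median log2 given). None held with an estimated correlation (adjusted p = 0.618 to 0.786). An offset of the 2 control libraries would give the same and cannot be told apart. Among neuronal lists, dopamine neuron genes differed by 0.47 (-0.45 without and 0.063 with AKG, adjusted p = 9.98e-06), postsynaptic genes by -0.55 (0.54 without and -0.030 with AKG, adjusted p = 9.57e-10) and presynaptic genes by -0.35 (0.34 without and -0.020 with AKG, adjusted p = 3.12e-04). Thalamus and midbrain excitatory genes differed by -0.51 (0.36 without and -0.16 with AKG, adjusted p = 0.01003) and forebrain excitatory genes by -0.49 (0.40 without and -0.036 with AKG, adjusted p = 0.0481). In the glial lists, disease-associated microglia genes differed by 0.57 (-0.42 without and 0.086 with AKG, adjusted p = 1.07e-05), homeostatic microglia genes by 0.28 (-0.20 without and 0.094 with AKG, adjusted p = 0.00497) and reactive astrocyte genes by 0.34 (-0.28 without and 0.046 with AKG, adjusted p = 0.00222). The oligodendrocyte lineage had 2 lists, as myelin genes differed by 0.32 (-0.13 without and 0.19 with AKG, adjusted p = 0.0249) and precursor genes by -0.25 (0.20 without and -0.038 with AKG, adjusted p = 0.0383). The myelin value of -0.13 was -0.43 and called without control library 1 (adjusted p = 1.51e-05), and 0.10 without control library 2. In immune lists, interferon genes differed by 0.36 (-0.39 without and -0.027 with AKG, adjusted p = 0.00521), MHC class I genes by 0.39 (-0.34 without and 0.050 with AKG, adjusted p = 0.00184) and complement genes by 0.56 (-0.36 without and 0.10 with AKG, adjusted p = 0.00339). For protein synthesis and respiration, ribosomal protein genes differed by 0.73 (-0.60 without and 0.12 with AKG, adjusted p = 6.55e-21) and respiratory chain genes by 0.51 (-0.43 without and 0.082 with AKG, adjusted p = 3.72e-17). Among metabolic and stress lists, TCA cycle and AKG metabolism genes differed by 0.12 (-0.090 without and 0.047 with AKG, adjusted p = 0.0257) and AKG-dependent dioxygenases by -0.13 (0.10 without and -0.016 with AKG, adjusted p = 0.0241). Lysosome genes differed by 0.14 (-0.15 without and 0.012 with AKG, adjusted p = 0.0169) and NRF2 genes by 0.41 (-0.32 without and 0.022 with AKG, adjusted p = 4.05e-04).

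Dopamine neuron genes were lower than in control in the vector group and in the AKG group, whose label names no vector. The vector alone would leave the AKG group near control, but its list median was -0.37 (Th -1.79 ± 0.13), which restates the pattern and is no new test. The list's mean differed from control by -0.57 ± 0.10 in the vector and -0.71 ± 0.10 in the AKG group (± standard error) and passed a t-test against the spread between libraries, also without control library 1 (-0.65 ± 0.12 and -0.79 ± 0.12) and with the length and GC trend removed (-0.53 ± 0.10 and -0.69 ± 0.10). Labels exchanged between libraries with and without the vector would leave 4 below the lowest control library, and 6 were, which the pattern already held. More or less of the neighbouring regions in the dissected piece cannot be told apart from the groups. The forebrain and thalamus list means went opposite to the dopamine mean: they were 3.48 and 3.69, and 3.22 and 3.83, in control and higher in all 6 others (3.85 to 4.15 and 3.87 to 4.21). This goes with control pieces that held more of the nigra, but it follows the groups. Within the 6, the dopamine mean and that of both lists together had Spearman rho -0.20 (exact permutation p = 0.714, adjusted p = 0.714 over 3 relations, Pearson r -0.122, exact p = 0.792, and r -0.307 without the 2 farthest), which decides nothing. A lower level in both treatments for a reason of biology, or an empty vector or injection in the AKG mice, also stays open, untested.

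Ribosomal protein, respiratory chain and postsynaptic genes were called against control in both the vector and the AKG group at camera's preset correlation, but none at an estimated one, and no list mean passed the t-test. In the AKG group these means differed from control by -0.37 ± 0.20 for respiratory chain, -0.63 ± 0.28 for ribosomal and 0.65 ± 0.25 for postsynaptic genes. Control library 1 alone cannot be told apart from an effect, since control is left with 1 library. Without it each list stayed called at the preset, and the smallest median, of respiratory chain genes in the AKG group, was -0.26, but no mean passed (-0.24 ± 0.25, -0.30 ± 0.21 and 0.31 ± 0.10 in that order). A trend with gene length and GC content, whose length part separated control from both groups, cannot be told apart either. With it removed all stayed called and the smallest median was -0.17, but no mean passed (-0.19 ± 0.13, -0.45 ± 0.19 and 0.40 ± 0.15). The presynaptic list lost its call without control library 1, with a smaller median of 0.012 in the AKG group, which is consistent with that library as the source. With the trend removed it was 0.27 and stayed called. Its mean, which failed before too, was 0.29 ± 0.20 and decides nothing. A difference between both control libraries and the rest, in dissection or RNA, or an effect of both treatments, was not tested.

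Whether chance can be excluded was asked for the averages over 4 against 4 libraries by refitting all 35 splits of the 8 libraries. Limma called 0 genes for the vector and for AKG, with 545 and 904 at an unadjusted p under 0.05 and 0 by voom. Every split reaches 0, so the 35 and 35 splits that gave as many genes decide nothing (the highest of the others gave 2). In these 2-group fits camera called 17 lists for the vector and 12 for AKG, and 14 and 29 splits gave as many, the highest of the others 23, so chance could not be excluded for these 2 counts. The split of both control libraries, AKG library 2 and combined library 2 from the rest, which follows no group, gave 2 genes and 21 lists.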

How the results depend on the processing

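Voom, protein-coding genes only and the removal of the length and GC trend were chosen only after the result was seen. Quantile normalization, median-of-ratios scaling, a minimum of 5 FPKM, voom and protein-coding genes only changed none of the 7 counts of genes. Without a filter (30505 genes) the counts were 5 for the vector against control, 6 for combined against vector, 12 for AKG against control, 14 for combined against AKG and 7 for the average vector effect, and besides Th these were genes with a mean of at most 0.336 FPKM such as Mir370. For AKG against control the count was 2 with a pseudocount of 0.1 and 2 without the length and GC trend, and 0 under eBayes without a trend, library weights or the replicate number as a block. The labels do not say that the replicate numbers pair the libraries, and correlations of replicate differences between groups ran from -0.32 to 0.34, and the block changed no other count of genes. Only the groups compared gave 1 gene there, Slc6a3 in place of Th. Leaving out 1 library gave 0 to 3359 genes for vector against control, 0 to 3376 for AKG against control, 0 to 1369 for the interaction, 0 to 692 for the average vector and 0 to 1304 for the average AKG effect, each highest without control library 2, where control library 1 alone stands for control. The cause of these changes was not tested. With an estimated correlation and by fry 0 lists were called in all 7 comparisons. No filter gave 5 lists for combined against vector, and the length and GC trend removed gave 12 for AKG against control. Other settings ended these list calls. A minimum of 5 FPKM ended MHC class II, dioxygenase, homeostatic microglia and oligodendrocyte precursor (vector against control), homeostatic microglia (combined against vector), interferon, lysosome, dioxygenase, homeostatic microglia, oligodendrocyte precursor and TCA cycle (AKG against control), dioxygenase, oligodendrocyte precursor, TCA cycle and myelin (interaction), dopamine neuron, MHC class II, lysosome, forebrain excitatory, heat shock and immediate early (average vector), disease-associated microglia and forebrain excitatory (average AKG). Quantile normalization ended lysosome, unfolded protein response and oligodendrocyte precursor (vector against control), lysosome, dioxygenase, oligodendrocyte precursor and TCA cycle (AKG against control), lysosome, oligodendrocyte precursor, TCA cycle and myelin (interaction), lysosome, unfolded protein response, heat shock and immediate early (average vector), disease-associated microglia (average AKG). No filter ended ribosomal, interferon, complement and homeostatic microglia (combined against vector), homeostatic microglia and cholinergic (AKG against control), thalamus and midbrain, homeostatic microglia and heat shock (combined against AKG), forebrain excitatory (interaction), disease-associated microglia (average AKG). Library weights ended lysosome, dioxygenase, homeostatic microglia, oligodendrocyte precursor, TCA cycle and cholinergic (AKG against control). The replicate block ended lysosome, dioxygenase and TCA cycle (AKG against control). Median-of-ratios scaling ended interferon (combined against vector), dioxygenase (AKG against control). Protein-coding genes only ended dioxygenase (AKG against control), forebrain excitatory (interaction). Voom and eBayes without a trend ended forebrain excitatory (interaction). A pseudocount of 0.1 ended thalamus and midbrain (combined against AKG). Leaving out 1 library gave 12 to 20 lists for AKG against control and 5 to 14 for combined against AKG. Calls were also gained. Without control library 1 these included myelin (-0.43) and blood (-1.03) in vector against control. In AKG against control they included myelin (-0.40), choroid plexus (0.61) and blood (-0.95), and in the interaction choroid plexus (-0.81) and blood (1.03). Others came in combined against AKG and both averages. Without control library 2 calls were gained in the same comparisons, and without each other library in some. The covariance of the vector and AKG differences from control ran from 0.0463 to 0.280. Lists that turned without 1 library had these median ranges. For vector against control, choroid plexus -1.88 to 0.30. For combined against vector, interferon 0.055 to 0.28, homeostatic microglia -0.0042 to 0.20, disease-associated microglia 0.036 to 0.38, myelin -0.036 to 0.59, respiratory chain -0.052 to 0.32 and ribosomal -0.060 to 0.28. For combined against AKG, respiratory chain -0.10 to 0.28, ribosomal -0.050 to 0.29, homeostatic microglia -0.042 to 0.20, myelin -0.10 to 0.49, choroid plexus -0.79 to 0.61, glucocorticoid 0.069 to 0.36 and thalamus -0.18 to -0.066. Where such a range keeps 1 sign (interferon, disease-associated microglia, glucocorticoid, thalamus) it was camera's direction that turned, against the sign of the median. With the length and GC trend removed the AKG-dependent dioxygenases in AKG against control had -0.021. The median standard error of a log2 difference was 0.150.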

Other observations

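The tests of choroid plexus were chosen only after the result was seen, while that of read depth was set beforehand. Genes of the choroid plexus, the epithelium that secretes cerebrospinal fluid, differed widely between libraries of the same group. Ttr was at 8778 and 435 FPKM in the control libraries, 44.0 and 1959 in the vector, 1334 and 2466 in the AKG and 53.4 and 4857 in the combined libraries. The folate receptor Folr1, at 0.695 to 37.1 FPKM, the water channel Aqp1, at 0.157 to 22.3, and the potassium channel Kcnj13, at 0.0853 to 12.6, ranked the libraries almost as Ttr did. Genes of the cilia of ependymal cells went another way: Foxj1 was at 42.4 FPKM in control library 1 and 13.2 to 18.4 in the other 7, Rsph1 at 42.0 and 9.86 to 18.2, and Ccdc153 at 40.1 and 5.93 to 13.3. Red blood cell genes were low in the same library, with Hba-a1 at 7.71 FPKM against 65.3 to 183, Hba-a2 at 0.854 against 9.45 to 26.0 and the heme synthesis gene Alas2 at 0.172 against 1.20 to 2.74.

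Different amounts of choroid plexus in the dissected pieces are a candidate explanation for the spread of Ttr. Over the 8 libraries Ttr and the mean of the other members of the fixed choroid plexus and ependyma list had Spearman rho 0.976 (exact permutation p = 3.97e-04, adjusted p = 0.00119 over 3 relations) and Pearson r 0.906 (exact permutation p = 1.24e-04), and r 0.936 without the 2 libraries farthest from the median. Read depth is argued against, since Ttr differed 91.0-fold between the combined libraries, whose reads differed by 5.22%, and Ttr and reads had rho -0.643 (exact permutation p = 0.0962, r -0.483 with exact p = 0.212, and r -0.0157 without the 2 farthest). No biological explanation was tested, as the spread lies within groups.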
